A study of Mus musculus with 384 samples.

How the data were processed

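Expression was profiled in macrophages grown from the bone marrow of male C57BL/6 mice, WT or Myd88 KO. Per the labels' protocols, the cells were transduced with a pool of reporter viruses on day 4, scraped and replated in wells on day 9, stimulated for up to 4 h and lysed. Libraries were 3′ digital gene expression libraries, a modified SCRB-Seq protocol finished with tagmentation and enrichment of transcript 3′ ends. The labels give plate, genotype, replicate, ligand and time for each well, and each well was mapped by these labels alone. The authors deposited whole-number counts per gene and well in 1 table of 23481 genes, of which 7381 have no count in any well. Per the submitters' processing notes, BWA was used and the build was mm10. The BWA version, the annotation, the counting program and how molecular tags were collapsed are not given in the sources used here. The deposited counts were tested as they are, with 0 columns of other samples in the table. Genes that share 3′ ends or near-identical sequence with another gene could be split by counting, and these counts cannot show it. Gene positions are from the GENCODE annotation of mm10, matched by symbol.

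Plate totals were 37323548 (WT replicate 1), 31280223 (WT replicate 2), 32320373 (KO replicate 1) and 29737092 counts (KO replicate 2). The ribosomal transcript Rn45s took 7.52%, 9.16%, 9.37% and 8.08% of them and was kept in the totals. No well repeated another: 0 wells were identical, and the chi-square per degree of freedom between the 2 wells of a group was 2.957 or more over 192 groups, with a median of 4.617. Wells of a plate were summed by time class, early (0.5 and 1 h), middle (1.5 and 2 h) and late (2.5, 3 and 4 h), and the 12 time 0 wells of a plate were summed over ligand labels. This gave 148 plate sums in 74 groups of 2 plates. Early sums held 207297 to 1048987 counts, middle sums 198344 to 1028058 and late sums 314684 to 1876446. A low total limits what can be called, and for a gene with no count in a group a fold would be a bound against a floor of 3 counts over the group. Such genes, and genes with 1 to 3 counts in a group, are given no fold here. Floors cover counting error only, and the interval given for the R848 wells covers scatter of wells about a fitted line.

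The sums were tested in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with a minimum count of 10, which left 10562, library sizes were scaled by TMM, and 1 quasi-likelihood model with robust dispersion was fitted to all groups. The median trended dispersion was 0.156 and the median prior degrees of freedom 56.68. All groups entered 1 fit because 2 plates per group give too few degrees of freedom alone. The comparisons were KO against WT at time 0, each ligand's late wells against time 0 in each genotype, each ligand's early wells against time 0 in WT, the difference between genotypes of the late changes and of the early LPS change, and MDP/LPS against LPS late. The early difference of the other ligands, and each ligand's early wells against time 0 in KO, were added after the data were seen. Middle wells entered the fit and the time courses. Benjamini-Hochberg adjustment was made within each comparison, with a threshold of 0.05. Of the 12 time 0 wells of a plate, each carries a ligand label although no time had passed. Over 48 time 0 wells a test by ligand label passed for 64 of 5789 genes (327 at an unadjusted p under 0.05), with a smallest edgeR adjusted p of 1.87e-07 for Psmd2, so the time 0 wells were not all alike.

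Plates carry their own name in the labels, and sums of 1 plate come from the same plate of cells, so plate within genotype was fitted as an alternative. The median correlation of a plate's deviations between groups was 0.01 in WT and 0.015 in KO, over 666 pairs each. Where that term changed a count by over 1.5 times, its value stands beside the result. In simulated counts with known changes, run on 10562 genes, the WT late LPS comparison called 1% of genes changed 2-fold and 36% of genes changed 4-fold, with 0 unchanged genes called. For the late LPS difference between genotypes the shares were 0% and 15%, with 0 unchanged genes called, so changes of 4-fold or less were mostly not detectable in that comparison. The simulated counts held no shared plate effect, no reads carried between wells and no time 0 difference. They therefore cannot tell how many false calls such sources would give.

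The genes named in the text follow a rule. It takes 24 fixed response genes in any comparison, and, among genes past the threshold with at least 30 counts that moved the same way in both plates, those with the highest and lowest log2 change, up to 10 on each side at time 0 and fewer for each ligand. It also takes up to 4 members with the smallest p of each fixed list. The 23 lists were NF-kB primary, late inflammatory, interferon-stimulated, IRF3 primary, immediate early, feedback and anti-inflammatory, NRF2 targets, hypoxia and glycolysis, cholesterol synthesis, LXR targets, ATF4 and unfolded protein, heat shock, oxidative phosphorylation, cell cycle, macrophage identity, receptors and adaptors, and markers of neutrophils, T and NK cells, B cells, dendritic cells, osteoclasts, stromal cells, and erythroid, mast cells and basophils. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation. Calls of a list in the text hold with the estimated correlation unless that p is printed. No marker list was tested against a reference of pure cells.

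The alternatives were DESeq2 1.42.0 on the same sums, RLE factors, no filter, a strict filter (mean of 10 counts), wells in place of sums, plate as a term, late wells from 2 h, and each plate left out in turn. Chosen after the data were seen were fits without 27 shallow wells (under 171280.5 counts, 0.5 of the median), with a plate-wide background subtracted, and with no time 0 term. Of the 27 wells 14 lay in KO replicate 2, 7 in KO replicate 1, 6 in WT replicate 2 and 0 in WT replicate 1. Dropping them left 1 plate for R848 in KO after time 0 and for early Pam3Cys in WT. The background took the mean profile of a plate, at the share of a mean well given by the 10th percentile of the time 0 level over the plate mean for 13 interferon-stimulated genes. That share was 24.96% and 28.26% in WT replicates 1 and 2, and 24.07% and 20.88% in KO replicates 1 and 2. Another scaling shifted the median of all genes by over 0.1 on the log2 scale in 1 of 63 comparisons, the early R848 difference, by 0.104.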

Results

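Gene expression was measured in bone-marrow-derived macrophages, cells grown from mouse marrow in macrophage growth factor. They came from wild-type mice (WT) and from mice with the Myd88 gene knocked out (KO). Myd88 is the adaptor protein through which most Toll-like receptors and the interleukin-1 receptor signal. The cells carried a pool of pathway reporter viruses. Each well received 1 of 12 innate immune ligands and was lysed 0, 0.5, 1, 1.5, 2, 2.5, 3 or 4 h later. Each genotype filled 2 plates of 96 wells, here called replicates 1 and 2, with 1 well per plate, ligand and time. The ligands were Pam3Cys (a synthetic bacterial lipopeptide), R848 (a small imidazoquinoline), CpG (bacterial-type DNA), LPS (lipopolysaccharide), Zymosan (yeast cell wall), Poly(I:C) (synthetic double-stranded RNA), MDP, and MDP with LPS. FLA, SeV, TDB and HT-DNA are printed as the labels give them. The profiles complement reporter measurements, per the design text, and the comparison of genotypes asks which ligand responses need Myd88.

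Total counts per well ran from 71720 to 767167 with a median of 342561, and a median of 9143.5 genes was detected. The plates held 37323548 (WT replicate 1), 31280223 (WT replicate 2), 32320373 (KO replicate 1) and 29737092 counts (KO replicate 2). Wells of 1 plate were summed before testing, into time 0 (12 wells) and, for each ligand, early (0.5 and 1 h), middle (1.5 and 2 h) and late (2.5, 3 and 4 h). Time 0 sums held 3167670 to 4901235 counts and late sums 314684 to 1876446, so time 0 levels are the more precise. The R848 wells of KO replicate 2 were the shallowest, with a mean of 102253 counts per well. Levels are CPM (counts scaled to a common total) as mean ± SD over the 2 plates of a genotype. Log2 changes carry their standard error (SE) and are scaled by TMM factors, so for a small change they can differ in sign from the CPM. Adjusted p-values come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 10562 genes. Each gene given with a log2 change moved the same way in 2 of 2 plates of each genotype compared, except Cxcl10 in the LPS difference and Tnf with LPS in KO, which was at -0.009 without KO replicate 1 and at 0.211 without KO replicate 2. The labels do not say that the plates came from separate mice or cultures, so edgeR p-values measure spread between plates. For each gene that spread was estimated over all groups of both genotypes together, not from the plates compared alone. With LPS the late count in KO fell without a WT plate, and in WT it rose without a KO plate. Counts of called genes therefore do not by themselves rank the responses of the genotypes. Camera p-values compare a list with the other genes under a preset correlation of 0.01, and do not measure the spread between plates. For NF-kB primary genes in late LPS levels, an estimated correlation of 0.1 turned a camera adjusted p of 1.38e-34 into 2.51e-08. Genotype cannot be told apart from plate.

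Myd88 lies on the minus strand of chromosome 9, from 119335934 to 119341411 (mm10). Over all wells its transcript stood at 15.1 and 18.2 CPM in the KO plates and at 46.0 and 47.7 in the WT plates. At time 0 the level was 15.75 ± 1.78 in KO and 32.72 ± 3.28 in WT, a log2 difference of -1.08 (SE 0.63) with an edgeR adjusted p of 1. In late LPS wells it was 9.56 ± 3.96 in KO and 81.45 ± 0.767 in WT, a log2 difference of -3.19 (SE 0.78, edgeR adjusted p 0.00836). The labels do not state which part of the gene was deleted. A 3′ tag outside the deleted part checks nothing, so these levels do not test the genotype labels.

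In time 0 wells, transcripts of inflammatory genes were counted at a lower level in KO than in WT. Il1b (interleukin 1 beta, chromosome 2, 129364570 to 129371139) stood at 36.75 ± 1.36 CPM in KO and 544.5 ± 84.5 in WT, a log2 difference of -3.92 (SE 0.43, edgeR adjusted p 3.42e-10). The acute-phase gene Saa3 differed by -5.91 (SE 0.76, edgeR adjusted p 2.32e-08) and the NF-kB cofactor Nfkbiz by -3.52 (SE 0.37, adjusted p 1.06e-12). The neutrophil-attracting chemokines Cxcl1 and Cxcl2 differed by -4.34 (SE 0.58) and -3.46 (SE 0.46), with an edgeR adjusted p of 2.76e-07 each. Ptgs2, the inducible prostaglandin synthase, differed by -4.49 (SE 0.74, edgeR adjusted p 6.45e-05). Tnf stood at 53.69 ± 0.897 in KO and 261.9 ± 10.5 in WT (log2 -2.31, SE 0.51, edgeR adjusted p 0.0108). In all, 29 genes differed, 0 higher and 29 lower in KO, with 239 at an unadjusted p under 0.05. Of the 40 NF-kB primary genes, 12 were lower, or 28 adjusted over the list alone (camera adjusted p 2.29e-97). The late inflammatory list had 3 of 19 lower, or 8 adjusted over the list alone (camera adjusted p 1.62e-30). The feedback and anti-inflammatory list had 3 of 18 lower, among them Socs3 (log2 -3.12, SE 0.50) and Il1rn (log2 -1.53, SE 0.35), or 5 adjusted over the list alone (camera adjusted p 7.02e-17). Among immediate early genes 0 of 26 passed, and 7 were lower adjusted over the list alone (camera adjusted p 3.55e-11). For macrophage identity genes the count was 0 of 24, also adjusted over the list alone (camera adjusted p 0.247). The count of 29 became 7 without WT replicate 1, 5 without WT replicate 2, 46 without KO replicate 1 and 41 without KO replicate 2. It was 643 with wells in place of plate sums, 51 without a filter on low counts, 44 without shallow wells and 0 after a plate-wide background was subtracted.

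In WT macrophages Pam3Cys, R848, CpG and FLA raised NF-kB genes in the late wells. Nfkbia, the NF-kB inhibitor that NF-kB itself induces (chromosome 12, 55489410 to 55492647), stood at 1017 ± 87.9 CPM at time 0. It reached 7163 ± 771 with Pam3Cys (log2 2.91, SE 0.25, edgeR adjusted p 5.23e-18) and 8981 ± 351 with R848 (log2 3.29, SE 0.25, adjusted p 3.42e-21). With CpG it reached 8588 ± 1570 (log2 3.26, SE 0.25, edgeR adjusted p 5.49e-21) and with FLA 3764 ± 505 (log2 1.97, SE 0.24, adjusted p 2.16e-09). Il1b rose with Pam3Cys (log2 3.13, SE 0.41), R848 (log2 3.10, SE 0.41) and CpG (log2 2.94, SE 0.40). Il12b, a subunit of interleukin 12, rose with R848 (log2 4.09, SE 0.61, edgeR adjusted p 2.02e-06) and CpG (log2 4.21, SE 0.62, adjusted p 1.51e-06). Sox4, a transcription factor gene, fell with Pam3Cys (log2 -4.20, SE 0.71, edgeR adjusted p 2.14e-05) and FLA (log2 -3.56, SE 0.68, adjusted p 0.000716). Of the 40 NF-kB primary genes, 27 rose with Pam3Cys, 30 with R848, 28 with CpG and 9 with FLA, or 35, 37, 34 and 20 adjusted over the list alone. Their camera adjusted p was 3.59e-75, 2.28e-83, 9.35e-84 and 2.05e-32. Of the 48 interferon-stimulated genes, 2 rose with R848, also adjusted over the list alone, Ifi205 among them (log2 2.08, SE 0.32). That list's camera adjusted p was 0.00595, and the adjusted p = 0.403 with an estimated correlation. Cell cycle genes were lower as a list with Pam3Cys (camera adjusted p 0.0078) and FLA (0.0104), with 0 of 30 called in either and 0 and 1 lower adjusted over the list alone. Over all genes 203 rose and 80 fell with Pam3Cys, 195 and 94 with R848, 162 and 59 with CpG, and 52 and 18 with FLA. Leaving out WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2 in turn gave 10, 15, 558 and 562 genes for Pam3Cys, 15, 26, 519 and 520 for R848, 15, 13, 461 and 466 for CpG, and 1, 2, 204 and 208 for FLA.

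**Figure D1:**
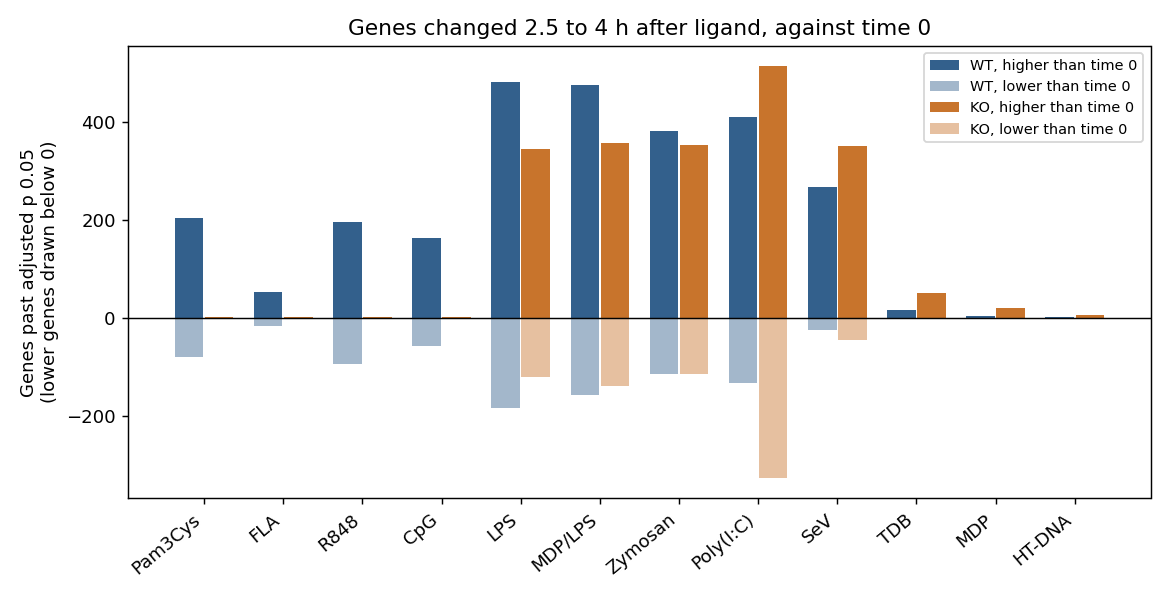
Number of genes past an adjusted p of 0.05 in the late wells (2.5 to 4 h) of each ligand against time 0, higher genes above 0 and lower genes below 0, WT in blue and KO in orange. With Pam3Cys 203 genes rose in WT and 1 in KO, while with Poly(I:C) 410 rose in WT and 513 in KO. Both genotypes share an estimate of spread, so a larger KO count does not by itself show a broader response.

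In KO macrophages the same ligands left Nfkbia near its time 0 level of 626.4 ± 0.944 CPM. Late Nfkbia stood at 928.6 ± 63.0 with Pam3Cys (log2 0.54, SE 0.23, edgeR adjusted p 1) and 760.0 ± 66.6 with R848 (log2 0.35, SE 0.24, adjusted p 1). With CpG it was 710.3 ± 81.7 (log2 0.20, SE 0.23, edgeR adjusted p 1) and with FLA 788.7 ± 157 (log2 0.39, SE 0.24, adjusted p 0.874). Of the 40 NF-kB primary genes 0 passed with each of these ligands, over all genes and adjusted over the list alone. Camera gave R848 an adjusted p of 6.63e-05, and the adjusted p = 0.0945 with an estimated correlation. Id3, which encodes an inhibitor of DNA binding, was the 1 gene called with Pam3Cys (log2 2.68, SE 0.31, edgeR adjusted p 1.6e-10) and with CpG (log2 2.82, SE 0.31, adjusted p 1.57e-11). R848 raised Id3 and Ncl, and FLA raised Id3 and lowered Prpf38b. Ncl and Prpf38b also differed between time 0 wells grouped by ligand label. Late FLA wells of KO replicate 1 held only 71720 to 191899 counts each, and R848 wells of KO replicate 2 a mean of 102253. Leaving out the other KO plate leaves these shallow wells alone, which cannot show a response of KO cells by themselves. The FLA count of 2 was 234 without KO replicate 2 and 1 without any other plate, and the R848 count of 2 was 460 without KO replicate 1 and 1 without KO replicate 2.

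The genotypes' late changes from time 0 were then tested against each other, so that lower means a smaller rise or a larger fall in KO, from a time 0 level that can itself differ. This difference was higher in KO for 8 genes and lower for 51 with Pam3Cys, 9 and 49 with R848, 8 and 49 with CpG, and 0 and 8 with FLA. Nfkbia was lower with Pam3Cys (log2 -2.38, SE 0.33, edgeR adjusted p 5.26e-07), R848 (log2 -2.94, SE 0.34, adjusted p 1.33e-10), CpG (log2 -3.06, SE 0.34, adjusted p 1.61e-11) and FLA (log2 -1.58, SE 0.33, adjusted p 0.0109). Il1b was lower with Pam3Cys (log2 -2.87, SE 0.57, edgeR adjusted p 0.00209) and CpG (log2 -3.03, SE 0.58, adjusted p 0.00131). The chemokine gene Ccl3 was lower with CpG (log2 -3.38, SE 0.47, edgeR adjusted p 3.51e-07) and R848 (log2 -2.52, SE 0.48). Tnfaip2, a TNF-induced gene, was lower with Pam3Cys (log2 -2.75, SE 0.39), R848 (log2 -2.16, SE 0.39) and FLA (log2 -2.21, SE 0.40). The protease Mmp14 differed by -3.38 (SE 0.79) with Pam3Cys and -3.44 (SE 0.86) with R848. Sox4, which fell in WT, differed by 4.01 (SE 0.90, edgeR adjusted p 0.00946) with Pam3Cys and 3.55 (SE 0.91, adjusted p 0.0425) with CpG. Of the 40 NF-kB primary genes, 15, 9, 14 and 4 were lower with Pam3Cys, R848, CpG and FLA, or 31, 28, 31 and 7 adjusted over the list alone. Their camera adjusted p was 1.37e-61, 1.05e-35, 2.44e-68 and 1.49e-12. The difference counts without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2 were 1, 2, 82 and 77 for Pam3Cys, 1, 1, 374 and 91 for R848, 1, 6, 84 and 76 for CpG, and 0, 0, 16 and 122 for FLA. With plate as a term within genotype the FLA count was 13, and after subtraction of a plate-wide background the counts were 9, 9, 17 and 3.

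LPS, MDP with LPS, and Zymosan raised both NF-kB and interferon-stimulated genes in WT. With LPS, late Il1b reached 5270 ± 115 CPM (log2 3.60, SE 0.41, edgeR adjusted p 1.63e-10) and Il12b 587.5 ± 95.6 (log2 4.32, SE 0.62, adjusted p 2.21e-07). The interferon-induced chemokine Cxcl10 reached 3586 ± 185 (log2 3.45, SE 0.53, edgeR adjusted p 7.9e-07). Ccl5 reached 2325 ± 222 (log2 4.52, SE 0.47) and the antiviral gene Rsad2 28680 ± 4196 (log2 4.24, SE 0.44), with an edgeR adjusted p of 5.79e-12 each. Il6 rose with LPS (log2 3.54, SE 0.89) and with MDP and LPS together (log2 4.56, SE 0.93). Zymosan raised Il1b (log2 3.64, SE 0.41) and Rsad2 (log2 2.95, SE 0.42). With LPS, MDP/LPS and Zymosan, 36, 37 and 37 of 40 NF-kB primary genes rose, or 39 each adjusted over the list alone (camera adjusted p 1.87e-68, 4.51e-79 and 1.06e-83). Interferon-stimulated genes rose in 39, 39 and 32 of 48, or 45, 43 and 40 adjusted over the list alone (camera adjusted p 5.76e-73, 3.63e-70 and 1.48e-50). IRF3 primary genes rose in 10, 10 and 9 of 11, or 10 each adjusted over the list alone. Feedback genes rose in 13, 15 and 12 of 18, or 14, 15 and 16 adjusted over the list alone, Il1rn (log2 3.24, SE 0.36) and Socs3 (log2 4.21, SE 0.47) among them with LPS. Over all genes 481 rose and 184 fell with LPS, 476 and 158 with MDP/LPS, and 381 and 116 with Zymosan. Dropping WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2 gave totals of 74, 155, 1032 and 1025 for LPS, 122, 125, 984 and 990 for MDP/LPS, and 45, 68, 808 and 813 for Zymosan.

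KO macrophages responded to the same 3 treatments. With LPS, Cxcl10 (log2 3.57, SE 0.53, edgeR adjusted p 5.97e-07), Ccl5 (log2 4.74, SE 0.48, adjusted p 2.03e-12) and Rsad2 (log2 4.45, SE 0.45, adjusted p 2.03e-12) rose. So did Irg1, the itaconate-making enzyme (log2 3.55, SE 0.48), Nfkbia (log2 2.70, SE 0.25, edgeR adjusted p 1.47e-16) and Il1b (log2 2.69, SE 0.42, adjusted p 1.65e-06). Late Tnf was 49.1 ± 4.85 CPM against 53.69 ± 0.897 at time 0 (log2 0.10, SE 0.56, edgeR adjusted p 0.971). Zymosan raised Cxcl10 (log2 3.56, SE 0.53), Rsad2 (log2 4.21, SE 0.44) and Il1b (log2 1.67, SE 0.41, edgeR adjusted p 0.00514), while Il12b gave log2 1.30 (SE 0.87, adjusted p 0.639). The numbers of genes up and down were 344 and 121 for LPS, 357 and 139 for MDP/LPS, and 353 and 115 for Zymosan. Subtraction of a plate-wide background lowered the totals for each of these treatments, most for Zymosan, as given in the section on processing. The genes that rose in both genotypes numbered 286 for LPS, 281 for MDP/LPS and 247 for Zymosan, where independent lists of these sizes would share 15.67, 16.09 and 12.73. NF-kB primary genes rose in 30, 33 and 30 of 40, or 34, 37 and 32 adjusted over the list alone. Interferon-stimulated genes rose in 39, 40 and 41 of 48, or 44, 43 and 45 adjusted over the list alone. The counts without WT replicate 1 and WT replicate 2 were 276 and 278 for LPS, 301 and 305 for MDP/LPS, and 281 both times for Zymosan.

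The late changes with LPS differed between genotypes in 2 genes, both with a lower change in KO. They were Cp, which encodes the copper protein ceruloplasmin (chromosome 3, 19957054 to 20009145; log2 -2.50, SE 0.49, edgeR adjusted p 0.011), and Pou2f2, a transcription factor gene (chromosome 7, 25087344 to 25179726; log2 -3.12, SE 0.64, adjusted p 0.0189). MDP/LPS gave Cp (log2 -2.91, SE 0.49, edgeR adjusted p 0.000281) and Pou2f2 (log2 -3.39, SE 0.67, adjusted p 0.00939), and Zymosan gave Rhou and Pou2f2 (log2 -3.05, SE 0.61, adjusted p 0.0303). The difference for Cxcl10 with LPS was 0.12 (SE 0.68, edgeR adjusted p 1), of mixed sign between plates, and for Il1b -0.90 (SE 0.55, adjusted p 1). As a list, feedback genes changed less in KO with LPS (camera adjusted p 2.74e-05), MDP/LPS (2.62e-06) and Zymosan (3.14e-06), with 0 of 18 called in each and 1, 2 and 1 adjusted over the list alone. The NF-kB list gave a camera adjusted p of 0.755 for LPS, with 0 of 40 called and 1 lower adjusted over the list alone. Interferon-stimulated genes with Zymosan had a larger change in KO as a list (camera adjusted p 1.66e-10), with 0 of 48 called and 0 adjusted over the list alone, and the adjusted p = 0.0651 with an estimated correlation. In late levels that list gave a camera adjusted p of 0.26. Omission of WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2 gave 0, 0, 11 and 4 genes for LPS, 0, 0, 32 and 1 for MDP/LPS, and 0, 0, 8 and 4 for Zymosan. After subtraction of a plate-wide background MDP/LPS and Zymosan gave 0.

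Late levels were also compared with no time 0 term, a choice made after the data were seen. With LPS, Il1b stood at 203.7 ± 30.2 CPM in KO and 5270 ± 115 in WT (log2 -4.82, SE 0.45, edgeR adjusted p 2.68e-13) and Tnf at 49.1 ± 4.85 and 596.4 ± 69.97 (log2 -3.72, SE 0.58, adjusted p 4.91e-06). Il12b stood at 43.74 ± 21.2 and 587.5 ± 95.6 (log2 -3.86, SE 0.65, edgeR adjusted p 4.18e-05) and Socs3 at 48.4 ± 1.47 and 521.6 ± 37.4 (log2 -3.55, SE 0.48, adjusted p 5.97e-08). At time 0 Il1b already differed by log2 -3.92 (SE 0.43), Tnf by -2.31 (SE 0.51), Il12b by -3.29 (SE 0.67) and Socs3 by -3.12 (SE 0.50). These late gaps include the time 0 gap and do not by themselves measure a response to LPS. The late log2 difference was -0.56 (SE 0.48, edgeR adjusted p 0.694) for Cxcl10, -0.55 (SE 0.41, adjusted p 0.638) for Ccl5 and -0.49 (SE 0.39, adjusted p 0.669) for Rsad2. Zymosan gave -5.89 (SE 0.47, edgeR adjusted p 1.61e-16) for Il1b and 0.65 (SE 0.48, adjusted p 0.671) for Cxcl10. Over all genes the late level was higher in KO for 26 genes and lower for 160 with LPS, 35 and 221 with MDP/LPS, and 24 and 152 with Zymosan. As a list, NF-kB primary genes had lower late levels in KO with LPS, MDP/LPS and Zymosan, with 16, 16 and 19 of 40 lower, or 25, 26 and 22 adjusted over the list alone (camera adjusted p 1.38e-34, 2.34e-28 and 8.21e-36). The NF-kB list was already lower in KO at time 0. Interferon-stimulated genes were lower in 2, 6 and 0 of 48, or 6, 9 and 0 adjusted over the list alone. That list gave a camera adjusted p of 1.23e-06 with LPS and 2.89e-06 with MDP/LPS, and the adjusted p = 0.167 in both with an estimated correlation. In single wells, Il1b with LPS went from 582.3 ± 221 at time 0 to 6117 ± 236 at 2 h and 5918 ± 201 at 4 h in WT. In KO it went from 41.25 ± 0.808 to 861.0 ± 54.8 at 1.5 h and 247.0 ± 155 at 4 h, as the time course plots show.

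**Figure D2:**
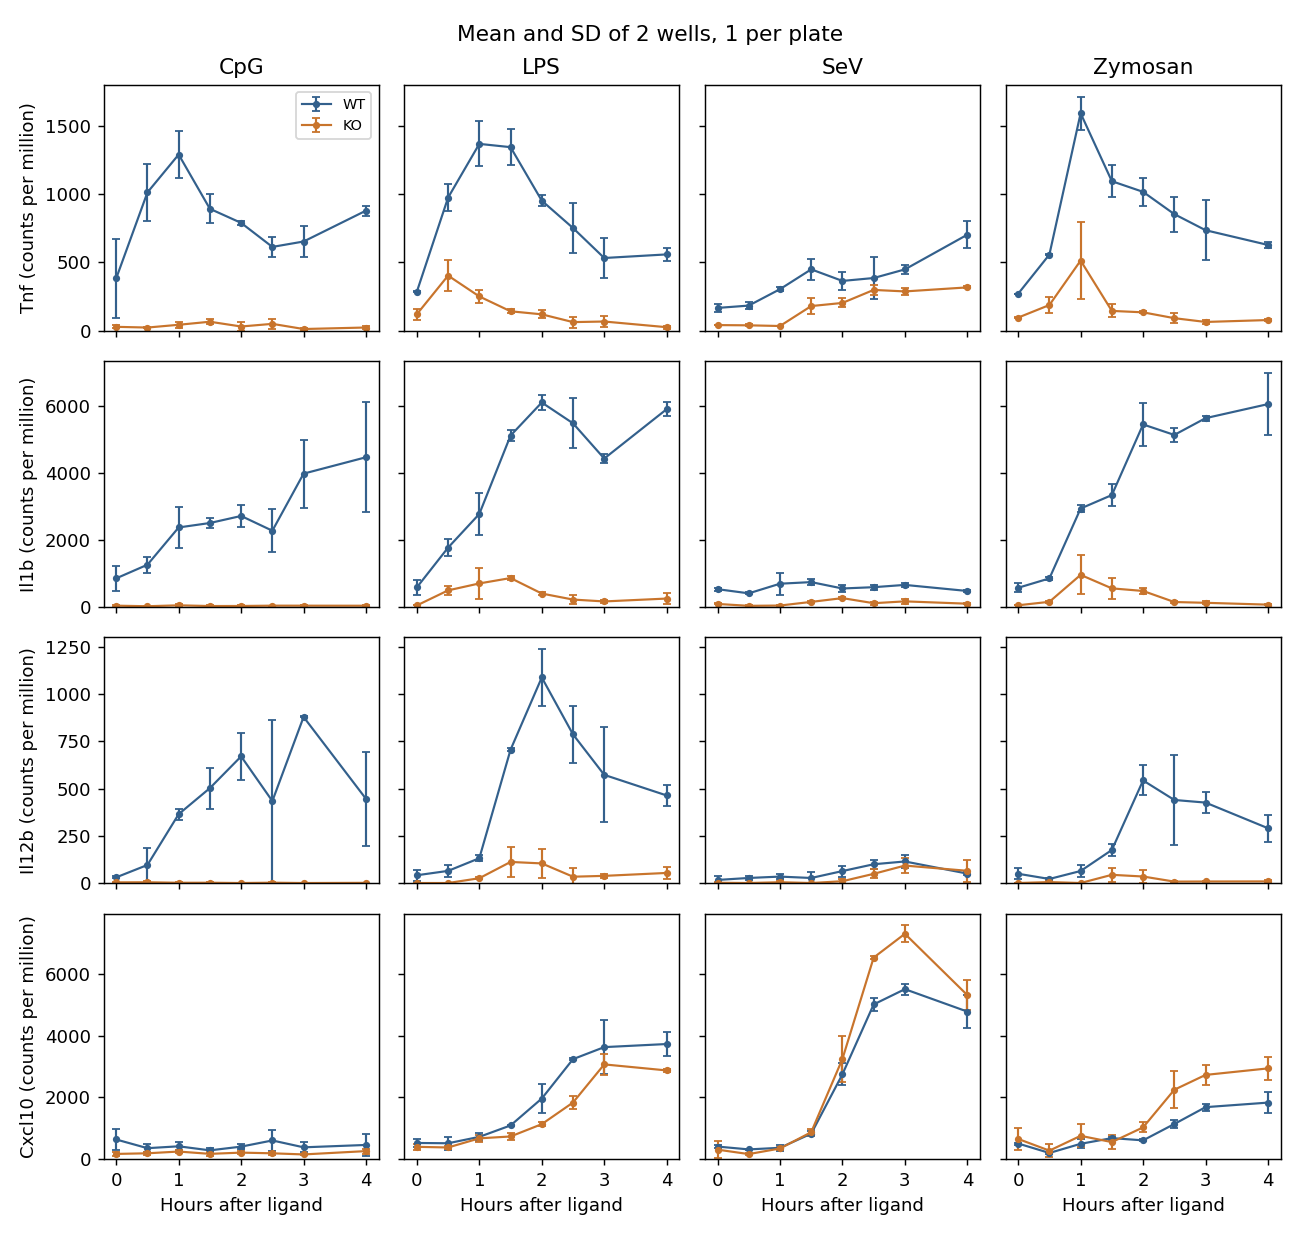
CPM of Tnf, Il1b, Il12b and Cxcl10 against hours after CpG, LPS, SeV or Zymosan, points and bars showing the mean and SD of 2 wells, 1 per plate, WT in blue and KO in orange. The Il1b course with LPS ends at 5918 in WT and 247.0 in KO at 4 h, while Cxcl10 with LPS ends at 3727 and 2873.

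Poly(I:C) and SeV raised interferon-stimulated genes in both genotypes. With Poly(I:C), Cxcl10 rose by log2 4.33 (SE 0.55, edgeR adjusted p 6.17e-09) in WT and 5.03 (SE 0.57, adjusted p 8.57e-11) in KO, and Ccl5 by 4.70 (SE 0.48) and 5.44 (SE 0.49). With SeV, Ifnb1, the interferon beta gene (chromosome 4, 88522025 to 88522774), rose to 175.7 ± 17.8 CPM in WT (log2 5.96, SE 1.34, edgeR adjusted p 0.002) and 363.6 ± 53.9 in KO (log2 6.52, SE 1.36, adjusted p 0.00056). Rsad2 rose with SeV by 4.87 (SE 0.46) and 5.30 (SE 0.47). Interferon-stimulated genes rose in 43 of 48 with Poly(I:C) and 42 of 48 with SeV in each genotype, or 46 each adjusted over the list alone (camera adjusted p 2.71e-97 and 1.15e-134 in WT). IRF3 primary genes rose in 9 of 11 with Poly(I:C) and 11 of 11 with SeV in each genotype, or 10 and 11 adjusted over the list alone. Poly(I:C) raised 410 and lowered 133 genes in WT, and 513 and 327 in KO. SeV raised 267 and lowered 25 in WT, and 350 and 45 in KO. Both genotypes were tested with a shared estimate of spread, so the larger KO counts do not show a broader response there. For both ligands the WT counts without a KO plate were larger than the KO counts without a WT plate. Subtraction of a plate-wide background lowered the totals for both ligands in both genotypes, as given in the section on processing. The genes that rose in both genotypes numbered 349 with Poly(I:C) and 232 with SeV, against 19.91 and 8.85 for independent lists. Leaving out WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2, Poly(I:C) gave 83, 96, 972 and 972 genes in WT and 489, 489, 687 and 636 in KO, and SeV 55, 63, 450 and 465 in WT and 263, 266, 338 and 320 in KO.

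The late difference between genotypes passed for 0 genes with Poly(I:C) and 0 with SeV in edgeR, with 116 and 145 genes at an unadjusted p under 0.05 and 1 gene each in DESeq2. As a list, NF-kB primary genes rose more from their lower time 0 levels in KO than in WT with SeV (0 of 40 called, 12 adjusted over the list alone, camera adjusted p 1.05e-25) and Poly(I:C) (0 called, 1 adjusted over the list alone, camera adjusted p 1.67e-20). In late levels with no time 0 term the same list was lower in KO, with 4 of 40 lower for SeV and 6 for Poly(I:C), or 7 and 11 adjusted over the list alone. The camera adjusted p was 4.14e-06 and 1.22e-12, and for SeV the adjusted p = 0.0722 with an estimated correlation. Late Il1b with SeV stood at 115.6 ± 24.7 CPM in KO and 558.3 ± 21.0 in WT (log2 -2.32, SE 0.41, edgeR adjusted p 0.000582), and late Tnf at 299.9 ± 3.85 and 533.3 ± 60.9 (log2 -0.88, SE 0.49, adjusted p 0.775). At time 0 Il1b already differed by log2 -3.92 (SE 0.43) and Tnf by -2.31 (SE 0.51), so these late gaps do not measure a response to SeV. Against time 0, Tnf with SeV gave log2 1.33 (SE 0.49, edgeR adjusted p 0.193) in WT and 2.76 (SE 0.52, adjusted p 7.16e-05) in KO. The count without KO replicate 1 and KO replicate 2 was 4 and 0 for Poly(I:C) and 5 and 6 for SeV, and it was 0 without either WT plate. With plate as a term SeV gave 1 gene.

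**Figure D3:**
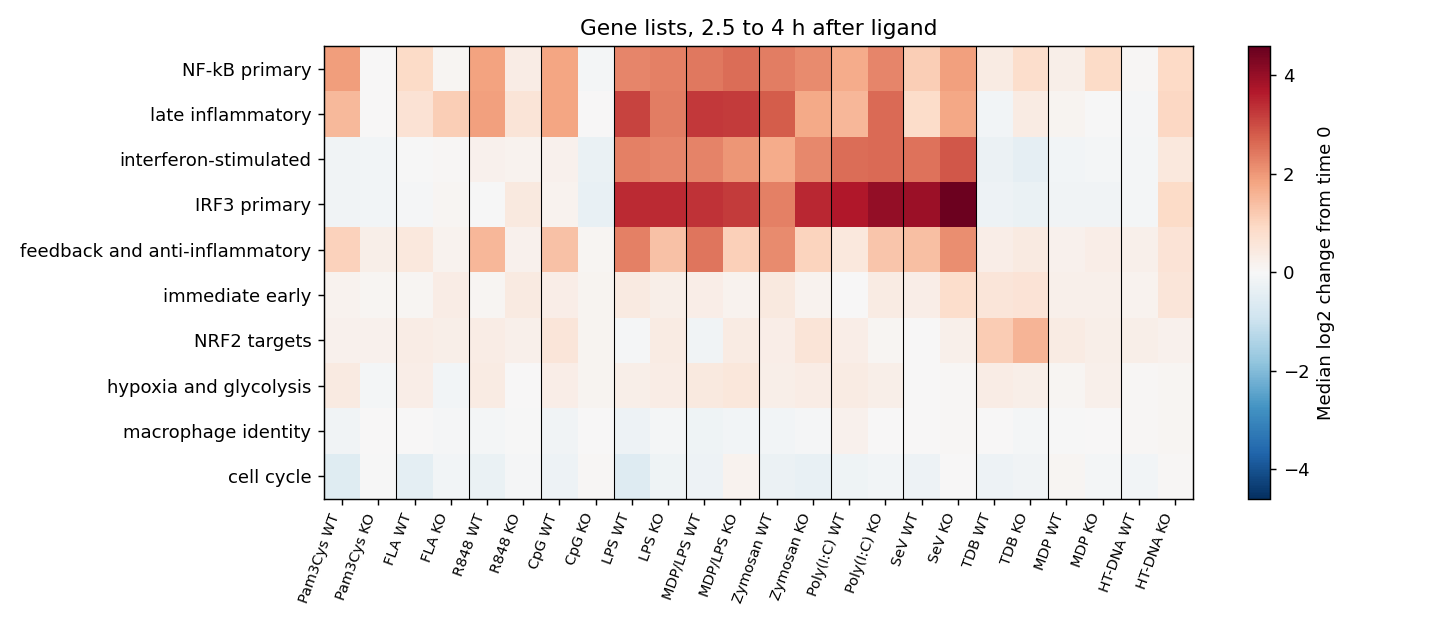
Median log2 change of the tested members of 10 fixed gene lists in late wells (2.5 to 4 h) against time 0, by ligand and genotype, red for higher and blue for lower; a member with no count in a group is set to a floor of 3 counts. NF-kB primary genes have a median of 1.91 with Pam3Cys in WT, 2.25 with LPS in WT and 2.32 with LPS in KO.

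TDB raised genes of the NRF2 antioxidant programme in both genotypes. Gclm, a subunit of the glutathione-synthesising ligase (chromosome 3, 122245557 to 122270732), rose to 1752 ± 64.8 CPM in WT (log2 3.23, SE 0.32, edgeR adjusted p 2.03e-14) and 1114 ± 21.0 in KO (log2 3.00, SE 0.31, adjusted p 8.5e-13). Its partner Gclc rose by 3.04 (SE 0.51) and 2.91 (SE 0.50), sulfiredoxin Srxn1 by 3.01 (SE 0.39) and 3.11 (SE 0.39), and the haem oxygenase Hmox1 by 2.15 (SE 0.33) and 1.81 (SE 0.33). Of 15 NRF2 targets 6 rose in each genotype, or 7 adjusted over the list alone (camera adjusted p 1.65e-38 in WT and 4.98e-32 in KO). For the difference between genotypes this list gave a camera adjusted p of 0.923. NF-kB primary genes rose in 2 of 40 in WT and 10 in KO, Cxcl2 among them (log2 3.38, SE 0.47, edgeR adjusted p 3.83e-07), or 6 and 19 adjusted over the list alone. Over all genes 15 rose in WT and 50 in KO, and 15 rose in both where independent lists would share 0.07. The larger KO count rests on a spread estimated over both genotypes and does not show a broader response there. The WT counts without a KO plate were larger than the KO counts without a WT plate. The 3 that fell in WT included Fam46a (log2 -1.72, SE 0.32) and the transcription factor Maf (log2 -1.19, SE 0.26), and the 3 that fell in KO included Sesn1 (log2 -1.58, SE 0.40). The difference between genotypes passed for 0 genes in edgeR, with 100 at an unadjusted p under 0.05 and 1 in DESeq2. Leave-one-out counts (WT replicate 1, WT replicate 2, KO replicate 1, KO replicate 2) were 1, 1, 47 and 46 in WT and 24, 24, 51 and 36 in KO.

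MDP and HT-DNA changed few genes. MDP raised 3 genes in WT: Id3 (log2 1.88, SE 0.30, edgeR adjusted p 7.72e-05), Gclm (log2 1.35, SE 0.30, adjusted p 0.0401) and Nfkbia (log2 1.09, SE 0.23, adjusted p 0.0401). In KO it raised 20 genes, among them Clec4e, a receptor for mycobacterial glycolipid (log2 2.65, SE 0.32, edgeR adjusted p 1.03e-09), Tlr2 (log2 2.62, SE 0.37) and Nfkbia (log2 1.91, SE 0.24), and lowered Kctd12b (log2 -3.75, SE 0.93). The larger KO count rests on a spread estimated over both genotypes. The WT counts for MDP without a KO plate were larger than the KO counts without a WT plate. NF-kB primary genes rose with MDP in 1 of 40 in WT and 8 in KO, or 5 and 13 adjusted over the list alone (camera adjusted p 1.04e-11 and 2.01e-35). HT-DNA raised Id3 (log2 2.35, SE 0.31, edgeR adjusted p 3.51e-08) and Pmepa1 (log2 3.67, SE 0.74) in WT. In KO it raised 6 genes, among them Id3 (log2 2.61, SE 0.32), Tnfaip3 (log2 1.75, SE 0.37) and Usp8 (log2 2.34, SE 0.42), of which Usp8 also differed between time 0 wells grouped by ligand label. Late HT-DNA wells of KO replicate 1 held only 95149 to 185982 counts each, so a fit that keeps that KO plate alone rests on shallow wells. The difference between genotypes passed for 0 genes with MDP and 0 with HT-DNA in edgeR, with 62 and 316 at an unadjusted p under 0.05 and 0 in DESeq2 for both. As a list, NF-kB primary genes rose more from their lower time 0 levels in KO than in WT with MDP (camera adjusted p 1.8e-10), TDB (1.01e-12) and HT-DNA (1.06e-10), with 0 of 40 called in each and 0, 1 and 0 adjusted over the list alone. In late levels with no time 0 term the list was lower in KO, with 9, 4 and 4 of 40 lower, or 14, 13 and 8 adjusted over the list alone (camera adjusted p 4.19e-21, 2.45e-18 and 2e-08). Late Il1b with MDP stood at 48.92 ± 15.8 CPM in KO and 477.9 ± 76.6 in WT (log2 -3.32, SE 0.43, edgeR adjusted p 2.55e-07). Il1b already differed at time 0 by log2 -3.92 (SE 0.43), so this late gap does not measure a response to MDP. Counts without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2 were 0, 0, 12 and 12 in WT and 9, 9, 24 and 14 in KO for MDP, and 0, 1, 3 and 3 in WT and 2, 2, 2 and 356 in KO for HT-DNA. The HT-DNA difference count without KO replicate 2 was 115, and 0 without each other plate.

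In the early wells immediate early and NF-kB genes rose in WT. With LPS, Nfkbia reached 14420 ± 1164 CPM (log2 3.94, SE 0.26, edgeR adjusted p 2.06e-26). The immediate early transcription factors Egr1 (log2 3.89, SE 0.68, edgeR adjusted p 9.71e-05) and Fos (log2 2.38, SE 0.38, adjusted p 1.03e-05) rose, and so did Cxcl2 (log2 3.81, SE 0.46), the phosphatase Dusp2 (log2 3.81, SE 0.48) and Tnf (log2 2.27, SE 0.50, adjusted p 0.00546). With LPS 14 of 26 immediate early genes and 16 of 40 NF-kB primary genes rose, or 17 and 24 adjusted over the list alone (camera adjusted p 9.73e-80 and 1.45e-77). In KO, where early wells were tested after the data were seen, the same lists gave 13 and 18, or 17 and 25 adjusted over the list alone. HT-DNA raised 1 gene in WT, Id3 (log2 1.64, SE 0.31, edgeR adjusted p 0.00447). The counts up and down over all genes in WT were 52 and 0 for LPS, 66 and 1 for MDP/LPS, 50 and 1 for CpG, 47 and 0 for R848, 43 and 0 for Pam3Cys, 38 and 0 for Zymosan, 30 and 0 for FLA and 20 and 1 for Poly(I:C). MDP, TDB and SeV gave 0 genes in edgeR, with 151, 115 and 125 at an unadjusted p under 0.05 and 2, 2 and 0 in DESeq2. With plate as a term MDP gave 1 gene and HT-DNA 2. Without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2 the counts were 2, 15, 83 and 81 for LPS, 10, 16, 109 and 111 for MDP/LPS, 6, 8, 85 and 83 for CpG, 5, 5, 92 and 95 for R848, 1, 10, 83 and 79 for Pam3Cys, 6, 5, 62 and 60 for Zymosan, 2, 1, 60 and 60 for FLA, 1, 2, 83 and 89 for Poly(I:C), and 0, 0, 3 and 3 for HT-DNA. MDP and SeV gave 1 gene each without KO replicate 1 or KO replicate 2, and TDB 1 without KO replicate 2.

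The early LPS response was compared between genotypes. The log2 difference of the changes for Il1b was 1.97 (SE 0.55, edgeR adjusted p 1). Its early level, compared with no time 0 term, was lower in KO, at 590.7 ± 289 CPM against 2263 ± 488 in WT (log2 -1.95, SE 0.39, edgeR adjusted p 0.0153). In this comparison of levels 0 genes were higher in KO and 10 lower, Cxcl2 among them (log2 -2.01, SE 0.43, edgeR adjusted p 0.018). At time 0 Il1b already differed by log2 -3.92 (SE 0.43) and Cxcl2 by -3.46 (SE 0.46), so these early gaps do not measure a response to LPS. The difference of the changes passed for 0 genes in edgeR, with 229 at an unadjusted p under 0.05 and 0 in DESeq2. As a list, NF-kB primary genes changed more from time 0 in KO (camera adjusted p 0.00155, 0 of 40 called, 1 adjusted over the list alone), and the adjusted p = 0.595 with an estimated correlation. The count was 7 without KO replicate 1, 2 without KO replicate 2 and 0 without either WT plate.

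The early changes with the other ligands were compared after the data were seen. Nfkbia changed less in KO with CpG (log2 difference -3.50, SE 0.34, edgeR adjusted p 1.39e-14), R848 (log2 -3.27, SE 0.34, adjusted p 8.11e-13), Pam3Cys (log2 -3.03, SE 0.34, adjusted p 3.2e-11) and FLA (log2 -2.81, SE 0.34, adjusted p 9.52e-10). With CpG its early level was 845.3 ± 34.0 CPM in KO and 14320 ± 877 in WT. The change was lower in KO for 15 genes with CpG, 6 with R848, 4 with Pam3Cys and 3 with FLA, and higher for 0. The others with Pam3Cys were Irf1, Prdm1 and Tnfaip3, and with FLA Nfkbiz and Tnfaip2. Of the 40 NF-kB primary genes 7, 3, 2 and 3 were among them, or 20, 4, 18 and 9 adjusted over the list alone (camera adjusted p 6.16e-47, 4.22e-08, 1.13e-32 and 3.71e-27). Of 26 immediate early genes the counts were 6, 2, 0 and 0, or 12, 12, 11 and 8 adjusted over the list alone (camera adjusted p 6.28e-35, 5.9e-16, 5.99e-15 and 4.22e-13). With Poly(I:C), Il1b (log2 2.93, SE 0.55, edgeR adjusted p 0.0114) and Socs3 (log2 3.20, SE 0.66, adjusted p 0.0276) rose more in KO, from lower time 0 levels. Early Il1b with Poly(I:C) stood at 410.8 ± 12.0 CPM in KO and 788.5 ± 115 in WT. MDP, MDP/LPS, TDB, SeV, Zymosan and HT-DNA gave 0 genes in edgeR and in DESeq2, with 182, 206, 170, 142, 333 and 127 at an unadjusted p under 0.05. Without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2 the counts were 1, 1, 26 and 15 for CpG, 1, 1, 385 and 12 for R848, 0, 1, 12 and 11 for Pam3Cys, 1, 1, 7 and 16 for FLA, 0, 0, 7 and 3 for Poly(I:C), 0, 0, 190 and 1 for Zymosan, 0, 0, 4 and 0 for MDP, 0, 0, 2 and 1 for MDP/LPS, and 0, 0, 1 and 0 for TDB. RLE factors moved the median of all genes in the R848 difference by 0.104, from -0.095 to 0.009, and with them Nfkbia was at -3.12 and the count was 3. The Nfkbia call with Pam3Cys ended without WT replicate 1 (log2 -1.95, edgeR adjusted p 0.299), and after subtraction of a plate-wide background the counts were 3 for CpG, 3 for R848, 2 for Pam3Cys, 2 for FLA and 0 for Poly(I:C).

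Adding MDP to LPS was compared with LPS alone in late wells of each genotype. Ccl3 stood at 2273 ± 164 CPM with both and 1495 ± 161 with LPS in WT (log2 0.62, SE 0.31, edgeR adjusted p 1), and at 382.5 ± 63.0 and 171.2 ± 25.8 in KO (log2 1.18, SE 0.34, adjusted p 0.339). In WT 0 genes passed in edgeR, with 206 at an unadjusted p under 0.05 and 0 in DESeq2. In KO 1 gene passed, the ribosomal protein gene Rpl5 (log2 1.54, SE 0.28, edgeR adjusted p 0.00119), with 4 in DESeq2. The NF-kB list was higher with MDP in WT (camera adjusted p 0.0235) and KO (0.0101), with 0 of 40 called and 0 and 1 adjusted over the list alone. The adjusted p = 0.295 in WT and 0.455 in KO with an estimated correlation. The KO count was 0 without either WT plate, 25 without KO replicate 1 and 4 without KO replicate 2.

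Other fixed lists moved with some ligands. Pattern recognition receptors and adaptors rose with LPS in 9 of 34 and fell in 2 in WT, or 13 and 3 adjusted over the list alone (camera adjusted p 3.98e-06). Hypoxia and glycolysis genes rose with Zymosan in 5 of 23 in WT, also adjusted over the list alone (camera adjusted p 0.000427). The heat shock list was higher with R848 in WT (1 of 11 called, 2 adjusted over the list alone, camera adjusted p 0.0018) and the ATF4 and unfolded protein list with TDB in WT (0 of 16 called, 1 adjusted over the list alone, camera adjusted p 0.000482). Oxidative phosphorylation genes were higher with Poly(I:C) in KO (2 of 24 called, 3 adjusted over the list alone, camera adjusted p 0.00182), and the adjusted p = 0.159 with an estimated correlation. At time 0, KO against WT, interferon-stimulated genes were lower as a list (1 of 48 called, also adjusted over the list alone, camera adjusted p 6.33e-14). LXR targets (0 of 9 called, camera adjusted p 0.0189), dendritic cell markers (0 of 7, 0.047) and osteoclast markers (0 of 6, 0.032) were lower, each with 0 adjusted over the list alone, and the adjusted p = 0.0551, 0.0988 and 0.0545 with an estimated correlation. Cholesterol synthesis genes (0 of 19 called, camera adjusted p 0.449), neutrophil markers (0 of 6, 0.252) and B cell markers (0 of 2, 0.466) did not pass, with 0 adjusted over the list alone. Of the T and NK cell list and of the erythroid, mast cell and basophil list 1 gene each was tested and 0 passed, and 0 stromal cell markers were tested.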

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

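The tests of the time 0 genes and of the R848 wells were chosen only after those results were seen, as were the early differences given here, while the tests of the late difference between genotypes were fixed in advance. The late change differed between KO and WT in 59 genes with Pam3Cys, 58 with R848, 57 with CpG and 8 with FLA by the test of the difference itself. It differed in 2 genes with LPS, 2 with MDP/LPS and 2 with Zymosan. The early change differed in 15 genes with CpG, 6 with R848, 4 with Pam3Cys, 3 with FLA and 2 with Poly(I:C). Without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2 the late counts were 1, 2, 82 and 77 for Pam3Cys, 1, 1, 374 and 91 for R848, 1, 6, 84 and 76 for CpG, 0, 0, 16 and 122 for FLA, 0, 0, 11 and 4 for LPS, 0, 0, 32 and 1 for MDP/LPS, and 0, 0, 8 and 4 for Zymosan. The early counts were then 1, 1, 26 and 15 for CpG, 1, 1, 385 and 12 for R848, 0, 1, 12 and 11 for Pam3Cys, 1, 1, 7 and 16 for FLA, and 0, 0, 7 and 3 for Poly(I:C).

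The first pattern is the 29 genes lower at time 0 in KO (7 without WT replicate 1, 5 without WT replicate 2, 46 without KO replicate 1 and 41 without KO replicate 2), with a median log2 difference of -2.31. Reads carried over from stimulated wells of the same plate may add to it, since WT plates held more of these transcripts after stimulation: carried reads would be nearly constant per well, whereas cell RNA scales with the well total. In 24 WT time 0 wells the summed counts of these genes rose with the well total with a log-log slope of 0.683 (SE 0.133), between the values set for either source, and without Malat1, which took 28.4% of those counts, the slope was 0.495 (SE 0.132), while for all 29 in 24 KO time 0 wells it was 0.715 (SE 0.122). After a plate-wide background was subtracted, 0 of the 29 passed, and of the 25 with counts left 22 stayed negative, with the median log2 difference going from -2.08 to -1.64 and the median SE from 0.428 to 0.966, so the calls ended by a smaller difference and by a larger error. Carried-over reads and lower resting expression in KO cells cannot be told apart here, because the slopes over all 29 lie between both limits in either genotype, the slope without Malat1 lies within its SE of the limit for carried reads, and the subtraction assumes a profile.

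The next pattern is in the R848 wells of KO replicate 2, where the interferon-stimulated genes made up 12152 CPM against 5525 to 6283 in the 5 other ligands of that plate without an interferon response. A response to R848 without Myd88 was not seen in KO replicate 1, where the R848 wells stood at 6033 CPM, inside the range of 5786 to 7457 of the same ligands. That rests on 1 plate, and the top of its range is the FLA wells, with a mean total of 224698, so it does not settle the question. A fixed number of reads from the rest of the plate may weigh more in these wells, which had a mean total of 102253. A line through 40 wells of the other ligands predicted 753.0 counts per well. The mean of the 8 R848 wells was 1243, a ratio of 1.65, above the 95% interval of the line for a mean of 8 wells (296.2 to 1210). Taken alone, that goes against the same fixed number in every well as the whole cause. It does not decide this, because the interval treats 8 wells of 1 plate as independent and may be too narrow. The margin is also small, and the line is extended below its lowest total of 185536. In 24 time 0 wells per genotype the counts of 13 strong interferon-stimulated genes had a log-log slope on the well total of 0.108 (SE 0.147) in KO and 0.474 (SE 0.141) in WT. Reads reaching these wells in another number stay open too and were not tested. Wide spreads of such genes between plates were not limited to R848. Ifit1 stood at 1236 ± 590 CPM in late KO HT-DNA wells, where KO replicate 1 held 95149 to 185982 counts per well. In early WT Pam3Cys wells it stood at 1017 ± 677 CPM, where WT replicate 2 held 106245 and 122510 counts per well.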

How the results depend on the processing

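The alternatives were fixed before the data were examined, apart from the fits without shallow wells, with a subtracted background and with no time 0 term, and apart from all those of the early differences of ligands other than LPS, which were chosen after seeing the data. Unless a construction is named, the cause was not tested. Of 818 counts of genes under an alternative, 436 lay within 1.5 times the reported count and 382 did not. Among the 382 are all 24 counts of levels with no time 0 term, which ask another question than the difference they are set against. For the named genes 5648 values were recomputed: 4786 kept direction and side of the threshold, 841 kept direction and lost the threshold, 14 gained it and 7 changed sign. Of the 841, 253 and 225 came without WT replicate 1 and WT replicate 2, 28 and 28 without KO replicate 1 and KO replicate 2, 201 with the background subtracted, 51 with late wells from 2 h and 31 with DESeq2. Leaving out a plate leaves a group with 1 plate, which is then assumed to vary like the other groups. The KO and difference counts for R848, FLA, late HT-DNA and early Zymosan rose most where the KO plate left held shallow wells. For early Zymosan these were the KO replicate 2 wells of 198040 and 79333 counts. Such counts cannot show a response of KO cells by themselves. In counts simulated at the depth of these sums, with 2 plates per group, 15% of genes changed 4-fold were called in the late LPS difference, and the share due to depth alone was not tested. Of 1500 tests of gene lists 390 passed, of which 262 also passed with an estimated correlation.

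The signs that changed were of values near 0. Cxcl10 in the late LPS difference was 0.12 and became -0.053 with wells, and it ran from -0.163 without WT replicate 2 to 0.356 without WT replicate 1 (-0.026 without KO replicate 2). Tnf in KO late LPS was 0.10 and became -0.074 with wells, -0.052 without shallow wells and -1.17 with the background subtracted, and it ran from -0.009 without KO replicate 1 to 0.211 without KO replicate 2. With the background subtracted, Cxcl2, Edn1, Il12b and Socs3 at time 0 gave no value, since no count was left. Named genes that the strict filter removed likewise gave none.

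With plate within genotype as a replicate block, the late difference gave 13 genes for FLA and 1 for SeV, and WT early wells gave 1 for MDP and 2 for HT-DNA. It moved no other count by over 1.5 times. Of 429 values of named genes it brought 1 past the threshold, Cebpd in the late LPS difference, took 1 from it, Ccl3 early with Pam3Cys in WT, and changed no other call of a named gene. In the 1240 list tests run with it, it took 2 of 324 list calls and added 2, none of them named in the report. The WT and KO plates share only a number (correlation 0.009 at time 0), and with that number as a replicate block time 0 gave 35 genes in place of 29.

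DESeq2 gave 440 for Pam3Cys, 153 for FLA, 344 for CpG, 32 for TDB and 5 for MDP late in WT. Late in KO the counts were 2 for Pam3Cys, 19 for FLA, 6 for R848, 2 for CpG, 82 for TDB, 43 for MDP and 23 for HT-DNA. The late difference gave 116 for Pam3Cys, 21 for FLA, 116 for R848, 119 for CpG, 6 for LPS, 1 for Poly(I:C), 1 for SeV and 1 for TDB. WT early wells gave 46 for FLA, 67 for Poly(I:C), 2 for TDB, 2 for MDP and 2 for HT-DNA. In MDP/LPS against LPS the count was 4 for KO. Early differences were 10 for Pam3Cys, 5 for FLA and 11 for R848.

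RLE factors gave 15 for HT-DNA late in KO. Counts in the late difference were 4 for LPS. Early in WT the counts were 1 for MDP and 2 for HT-DNA, and the early difference for R848 was 3.

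Fits with no filter gave 51 at time 0. Late in KO the counts were 3 for Pam3Cys, 10 for R848 and 36 for HT-DNA. The late difference gave 22 for FLA, 12 for LPS, 4 for MDP/LPS, 8 for Zymosan, 3 for Poly(I:C), 4 for SeV, 2 for TDB and 4 for HT-DNA. WT early wells gave 1 for SeV and 4 for HT-DNA. In MDP/LPS against LPS the counts were 1 for WT and 5 for KO. The early difference gave 1 for LPS, 20 for Pam3Cys, 12 for FLA, 19 for R848, 26 for CpG, 4 for Poly(I:C), 1 for MDP/LPS and 1 for Zymosan.

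The strict filter gave 17 for HT-DNA late in KO. Counts in the late difference were 4 for LPS and 1 for SeV. Early in WT the counts were 1 for TDB, 1 for MDP and 2 for HT-DNA.

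Wells in place of plate sums, which by construction treat wells of a plate as replicates, gave 643 at time 0. Late in WT the counts were 915 for Pam3Cys, 368 for FLA, 820 for R848, 735 for CpG, 1511 for LPS, 1478 for MDP/LPS, 1183 for Zymosan, 1514 for Poly(I:C), 657 for SeV, 84 for TDB, 27 for MDP and 7 for HT-DNA. Late in KO the counts were 14 for Pam3Cys, 285 for FLA, 24 for R848, 5 for CpG, 1326 for LPS, 1411 for MDP/LPS, 1164 for Zymosan, 2073 for Poly(I:C), 888 for SeV, 225 for TDB, 117 for MDP and 255 for HT-DNA. The late difference gave 310 for Pam3Cys, 168 for FLA, 332 for R848, 301 for CpG, 40 for LPS, 96 for MDP/LPS, 32 for Zymosan, 1 for Poly(I:C), 9 for SeV and 2 for TDB. WT early wells gave 75 for Pam3Cys, 57 for FLA, 97 for R848, 83 for CpG, 86 for LPS, 117 for MDP/LPS, 73 for Zymosan, 94 for Poly(I:C), 5 for MDP and 4 for HT-DNA. In MDP/LPS against LPS the count was 5 for KO. Early differences were 7 for Pam3Cys, 5 for FLA, 26 for R848, 4 for Poly(I:C) and 1 for MDP/LPS.

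Late wells from 2 h gave 308 for Poly(I:C) and 192 for SeV late in WT. Late in KO the counts were 1 for FLA, 559 for Poly(I:C), 252 for SeV, 31 for TDB and 1 for HT-DNA. Counts in the late difference were 4 for FLA, 34 for R848, 31 for CpG and 1 for Zymosan.

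Fits without shallow wells gave 44 at time 0. They held 1 plate for R848 in KO after time 0 and for early Pam3Cys in WT. Late in WT the counts were 117 for FLA and 28 for TDB. Late in KO the counts were 1 for FLA, 1 for R848, 33 for MDP and 15 for HT-DNA. The late difference gave 18 for FLA, 1 for SeV and 1 for TDB. WT early wells gave 1 for SeV, 1 for MDP and 2 for HT-DNA. In MDP/LPS against LPS the count was 5 for KO. Early differences were 10 for Pam3Cys and 4 for Poly(I:C).

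Subtraction of the background gave 0 at time 0. Late in WT the counts were 59 for Pam3Cys, 17 for FLA, 75 for R848, 93 for CpG, 329 for LPS, 263 for MDP/LPS, 181 for Zymosan, 125 for Poly(I:C), 89 for SeV and 8 for TDB. Late in KO the counts were 1 for R848, 244 for LPS, 218 for MDP/LPS, 90 for Zymosan, 161 for Poly(I:C), 107 for SeV, 8 for TDB, 6 for MDP and 2 for HT-DNA. Counts in the late difference were 9 for Pam3Cys, 3 for FLA, 9 for R848, 17 for CpG, 0 for MDP/LPS and 0 for Zymosan. Early in WT the counts were 18 for Pam3Cys, 17 for FLA, 24 for R848, 25 for CpG, 27 for LPS, 37 for MDP/LPS, 24 for Zymosan, 10 for Poly(I:C), 1 for TDB and 1 for MDP. In MDP/LPS against LPS the count was 9 for KO. Early differences were 2 for Pam3Cys, 3 for R848, 3 for CpG and 0 for Poly(I:C).

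Levels of KO against WT with no time 0 term ask another question than the difference of changes, since they include the time 0 gap. In late wells they gave 617 for Pam3Cys, 427 for FLA, 673 for R848, 635 for CpG, 186 for LPS, 256 for MDP/LPS, 176 for Zymosan, 10 for Poly(I:C), 9 for SeV, 9 for TDB, 21 for MDP and 7 for HT-DNA. In early wells these levels gave 10 for LPS, 256 for Pam3Cys, 160 for FLA, 149 for R848, 139 for CpG, 14 for MDP/LPS, 77 for Zymosan, 5 for Poly(I:C), 20 for SeV, 27 for TDB, 22 for MDP and 16 for HT-DNA.

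With 1 plate left out, counts ran from 5 to 46 at time 0. The range late in WT was 10 to 562 for Pam3Cys, 1 to 208 for FLA, 15 to 520 for R848, 13 to 466 for CpG, 74 to 1032 for LPS, 122 to 990 for MDP/LPS, 45 to 813 for Zymosan, 83 to 972 for Poly(I:C), 55 to 465 for SeV, 1 to 47 for TDB, 0 to 12 for MDP and 0 to 3 for HT-DNA. The range late in KO was 1 to 234 for FLA, 1 to 460 for R848, 276 to 458 for LPS, 301 to 518 for MDP/LPS, 281 to 412 for Zymosan, 489 to 687 for Poly(I:C), 263 to 338 for SeV, 24 to 51 for TDB, 9 to 24 for MDP and 2 to 356 for HT-DNA. The range in the late difference was 1 to 82 for Pam3Cys, 0 to 122 for FLA, 1 to 374 for R848, 1 to 84 for CpG, 0 to 11 for LPS, 0 to 32 for MDP/LPS, 0 to 8 for Zymosan, 0 to 4 for Poly(I:C), 0 to 6 for SeV and 0 to 115 for HT-DNA. The range early in WT was 1 to 83 for Pam3Cys, 1 to 60 for FLA, 5 to 95 for R848, 6 to 85 for CpG, 2 to 83 for LPS, 10 to 111 for MDP/LPS, 5 to 62 for Zymosan, 1 to 89 for Poly(I:C), 0 to 1 for SeV, 0 to 1 for TDB, 0 to 1 for MDP and 0 to 3 for HT-DNA. The range in MDP/LPS against LPS was 0 to 25 for KO. The range in the early difference was 0 to 7 for LPS, 0 to 12 for Pam3Cys, 1 to 16 for FLA, 1 to 385 for R848, 1 to 26 for CpG, 0 to 2 for MDP/LPS, 0 to 190 for Zymosan, 0 to 7 for Poly(I:C), 0 to 1 for TDB and 0 to 4 for MDP.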

Other observations

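In KO the response of Tnf to LPS was short. It stood at 402.3 ± 112 CPM at 0.5 h, 249.8 ± 45.5 at 1 h and 24.84 ± 12.2 at 4 h (SD, n = 2 wells), while in WT it stood at 972.9 ± 100 at 0.5 h, 1366 ± 165 at 1 h and 557.4 ± 47.1 at 4 h. With SeV, Cxcl10 stood at 7293 ± 277 in KO and 5502 ± 182 in WT at 3 h, and its late levels were not told apart by the test (log2 difference 0.26, SE 0.48, edgeR adjusted p 0.973). Among genes with the highest change with SeV were the chemokine gene Cxcl9 in WT (log2 6.11, SE 0.77, edgeR adjusted p 3.99e-09) and Ifnb1 in KO (log2 6.52, SE 1.36, adjusted p 0.00056), where the monocyte-attracting chemokine Ccl12 also rose (log2 6.15, SE 0.78). With Poly(I:C) those named as highest in WT were Gm14446 (log2 5.39, SE 0.62), AW112010 (log2 5.15, SE 0.54) and the chemokine gene Cxcl11 (log2 5.02, SE 0.73).

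Time 0 wells were not all alike between ligand labels. Tnf was 119.8 ± 40.9 CPM in the KO time 0 wells labelled LPS, against 53.69 ± 0.897 over all KO time 0 wells, and 40.27 ± 2.21 in those labelled SeV (SD, n = 2). These wells were not compared by a test for this gene alone.

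Id3 rose with ligands that changed little else. It passed early in 11 of the 12 ligands in KO and 9 in WT, and late in 10 and 8. All ligands of a genotype were set against the same time 0 sums, so these are not separate findings. The late log2 change in KO was 2.68 (SE 0.31) with Pam3Cys and 2.61 (SE 0.32) with HT-DNA. Untreated wells at later times were not analysed here, and no explanation was tested.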
